A study of Mus musculus with 8 samples.

How the data were processed

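Gene expression was measured in primary articular chondrocytes, the cells that make and maintain joint cartilage. The cells came from the femoral condyles and tibial plateaus of 5-day-old wild-type ICR mice and were grown as a monolayer. They were infected either with an empty control adenovirus (Ad-null) or with an adenovirus carrying HIF-2alpha (Ad-Epas1), the hypoxia-inducible transcription factor encoded by Epas1. RNA was taken 24 hours after infection, and 4 samples of each kind, named biological replicates by the submitters, were labelled with biotin and hybridised to 8 whole-transcript arrays. Uninfected cells and protein levels were not analysed here.

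The deposited table holds log2 values for 41345 probe sets on each of the 8 arrays. The authors obtained them with RMA, per the submitters' processing notes. RMA corrects the background of each array, brings the arrays to a common distribution and summarises the probes of a probe set into one value. The RMA version and options, the array software, the probe set definition and the genome build are not given in the sources used here. The values carry no detection call, so a dim probe set has no bound below which its level is unreliable. RMA compresses differences at the dim end, and a fold from a dim level depends on its background correction. Control probe sets could not be told apart by name and stayed in the tests. All columns of the table belonged to these samples. The number of arrays limits the precision of each value.

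Genes were named from the platform annotation, which listed 1 gene symbol for 23521 probe sets, several for 1814 and none for 16010. The last are unnamed here, not without a gene, and no gene was named from a probe set with several symbols, except for further probe sets of Meg3. A gene with several probe sets was represented by the one with the highest mean over the 8 arrays, which gave 22180 genes. Current and older symbols were matched through a RefSeq gene table of the mouse assembly GRCm38.p6, which also gave the order of genes along chromosomes. No coordinates are given, because the build behind the array annotation is not known.

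The deposited log2 values were used as they stood, without further normalization. Ad-Epas1 was compared with Ad-null in limma 3.58.1 under R 4.3.3, with lmFit and eBayes without a trend and without a replicate block. The tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all 41345 probe sets, and the threshold was an adjusted p under 0.05. Every adjusted p given for a gene comes from this limma test unless another is named. Changes are Ad-Epas1 minus Ad-null on the log2 scale with 95% intervals or standard errors (SE) from limma, and folds are derived from them. The level of Epas1 was also compared by an exact two-sided permutation test. Simulated data had the means and spread of these 41345 probe sets, with noise drawn independently for each. Changes were planted only in probe sets at or above the median brightness. The limma step recovered 21.2% of 66 changes of 0.5, 70.1% of 67 changes of 1 and 95.5% of 67 changes of 2 on the log2 scale. It made 8 false calls among 133. Far fewer probe sets were changed there than passed in the data, so the adjusted threshold was stricter in the simulation. These shares therefore check the step but do not give the sensitivity of the reported test, and they do not cover dim probe sets.

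The test, the threshold, the other settings to be tried, 29 gene lists and the rule for named genes were fixed before the data were examined. The rule named Epas1, the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold whose groups did not overlap, 17 chosen genes whatever their result, and up to 4 members of each list that passed with the largest change. Predicted genes, RIKEN and Gm clones and small RNA genes were left out of the 10 largest changes. Other list members named in the text serve as examples and were chosen after their values were seen. Of 508 listed symbols, 467 matched a probe set, 7 of them through another symbol, and Epas1 was in no list. Each list was tested with camera, which sets its members against all other genes, first with a preset correlation between genes of 0.01 and then with a correlation estimated from the arrays. The fry test asked whether the members of a list moved, on balance, one way, and does not compare them with other genes. The p-values of these lists were adjusted over the 29 lists. A further 8 lists were written after the leading genes had been seen, 4 of them before the values of their own members had been seen. The p-values of the further lists were adjusted over those 8 alone, so they are not on the same scale as those of the 29.

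The replicate numbers 1 to 4 occur in both groups, and the labels name no shared animal or day behind them. Deviations from the group means were correlated between arrays of the same number, over all probe sets. These correlations were 0.146, 0.173, 0.37 and 0.105, with a mean of 0.198, and the mean for arrays with different numbers was -0.066. Deviations from a group mean cancel within the group, so the mean of -0.066 largely follows from that of 0.198 and is not a separate baseline. Of the 4 Ad-null arrays, 3 were closest to the Ad-Epas1 array with their own number. All 4 values exceeded 0.1, the level set for treating the numbers as pairs, so the result with the replicate number as a block is given wherever it changes the call of a named gene or of a list test. That level was set in advance, although the count from the blocked test became known together with the correlations.

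The other settings were the replicate block, a variance trend with robust estimation, quantile normalization of the values again, centring each array on its median, a test over only the probe sets at or above the median brightness, array weights (with statmod 1.5.0), leaving out each array in turn, an unequal-variance test per probe set, 1 probe set per gene, the mean over the probe sets of a gene, and the other list tests. Leaving out the replicate 3 arrays of both groups was added after seeing the data, because they stood apart on the second principal component. The unequal-variance test was planned for the number of probe sets and extended afterwards to named genes and list members.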

Results

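The arrays compared chondrocytes infected with Ad-Epas1 (n = 4) with chondrocytes infected with the control virus Ad-null (n = 4), and so asked which transcripts differ when HIF-2alpha is supplied to cartilage cells for 24 hours. The median log2 value of the 8 arrays lay between 5.04 and 5.11. Correlations between arrays were 0.9827 to 0.9874 over the 12 pairs within a group and 0.9716 to 0.9824 over the 16 pairs between groups. The first principal component held 35% of the variance and separated the groups, and the second held 18.9% and placed the replicate 3 arrays of both groups at -36.4 and -38.1, apart from the rest. The p-values measure the spread between samples that the submitters call biological replicates.

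**Figure D1:**
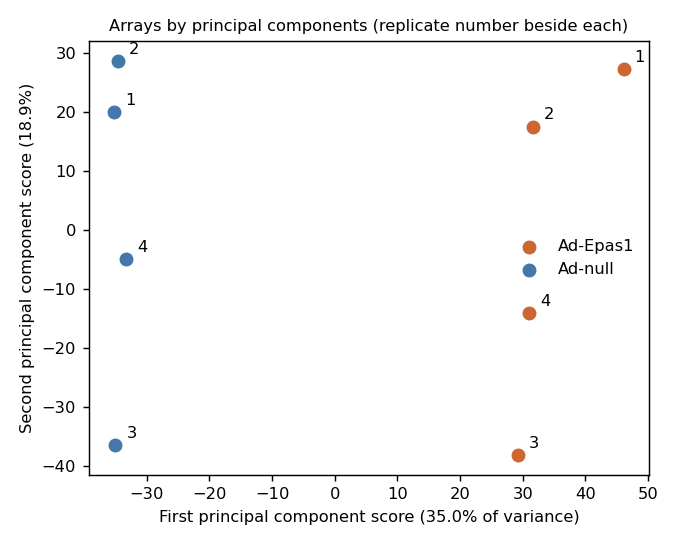
Scores of the 8 arrays on the first (horizontal) and second (vertical) principal components of the log2 values, with the share of variance on each axis and the replicate number beside each point. The 4 Ad-null arrays lie between -35.2 and -33.3 on the first component and the 4 Ad-Epas1 arrays between 29.3 and 46.1.

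Epas1 itself was measured at 6.91 ± 0.15 (log2, SD, n = 4) in Ad-null cells and 12.78 ± 0.19 (SD, n = 4) in Ad-Epas1 cells, a 58.6-fold rise. The change of 5.87 on the log2 scale had an SE of 0.12 and an adjusted p of 1.2e-07 in limma. The Ad-null values ranged from 6.75 to 7.09 and the Ad-Epas1 values from 12.6 to 12.96, and an exact two-sided permutation test gave p = 0.0286, the smallest value that 4 arrays against 4 allow. The permutation did not keep equal replicate numbers together, and 4 pairs would be too few for a two-sided p under 0.05. The probe set cannot tell the transcript of the virus from that of the cells' own gene.

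In Ad-Epas1 chondrocytes genes of matrix-degrading enzymes, cytokines and chemokines rose by up to 117-fold, genes of the hypoxia response, glycolysis and the cell cycle rose together, and most of the listed cartilage matrix genes fell. Mmp3, which encodes the matrix-degrading enzyme stromelysin 1, rose 117-fold, from 5.38 ± 0.56, a level not shown to exceed background, to 12.25 ± 0.15 (log2, SD, n = 4, adjusted p = 3.3e-06). Mmp13, a collagenase that cleaves type II collagen, rose 25.4-fold to 13.14 ± 0.06 (SD, n = 4, adjusted p = 2.2e-05). Matn1, which encodes the cartilage matrix protein matrilin 1, fell 4.06-fold, from 12.49 ± 0.06 to 10.47 ± 0.34 (SD, n = 4, adjusted p = 0.00013). In all, 2869 of 41345 probe sets (6.9%) passed an adjusted p under 0.05 in limma, 1467 higher and 1402 lower in Ad-Epas1 cells. The change reached 1 on the log2 scale for 458 of the higher and 211 of the lower probe sets, and reached 3 for 46 and 2. Counted by gene, 2368 of 22180 passed, 1220 higher and 1148 lower. The values of the groups did not overlap for 6135 probe sets (14.8%), where chance gives 2.86%. With the replicate block 2407 probe sets passed, 2130 of them shared with the 2869. Without the replicate 3 arrays of both groups 1649 probe sets passed, 955 higher and 694 lower.

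Among the 10 genes with the largest rises were the acute-phase genes Saa2 and Hp, Lbp, whose product binds bacterial lipopolysaccharide, and the neutrophil-attracting chemokine genes Cxcl3 and Cxcl5. Saa2, a serum amyloid A gene, rose 95-fold (log2 change 6.57, SE 0.31), Cxcl3 80.9-fold (6.34, SE 0.24), Hp, which encodes haptoglobin, 62.3-fold (5.96, SE 0.14), Cxcl5 41.7-fold (5.38, SE 0.14) and Lbp 22.7-fold (4.5, SE 0.14). Egln3, an oxygen-sensing prolyl hydroxylase that marks HIF proteins for degradation, rose 46.1-fold (5.53, SE 0.16). Nos2, the inducible nitric oxide synthase, rose 32.7-fold (5.03, SE 0.24), and Fabp4, which encodes a fatty acid binding protein, rose 22.8-fold (4.51, SE 0.38). The other two of the 10 were Mmp3 and Mmp13, and the adjusted p of the 10 genes in limma lay between 2.5e-07 and 2e-04. Hepatocyte and neutrophil markers, 26 genes of cells not meant to be in these cultures, reached 5.84 in Ad-null cells (Apoa1), and 7 of the 10 genes started no higher: Mmp3, Saa2 (3.49), Cxcl3 (2.76), Hp (5.68), Egln3 (5.27), Nos2 (5.37) and Fabp4 (4.12). Their folds depend on the background correction and are not exact, and the same holds for the rises of Adm (5.28), Il6 (3.91), Mmp12 (4.24), Mmp9 (5.27), Serping1 (4.89), Ptges (5.56), Arg2 (5.28), Birc5 (4.36) and other genes given below, 21 of the 66 named genes that rose. Serum amyloid and Cxcl genes have close relatives that probes may share. Genes given below that lay under Apoa1 (5.84) in both groups and did not pass may be too dim to show a change.

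The largest fall was that of Sfrp5, a secreted antagonist of Wnt signalling, which dropped 15.4-fold from 9.17 ± 0.3 to 5.23 ± 0.31 (log2, SD, n = 4, limma adjusted p = 1.3e-05). Il17b, a cytokine gene of the interleukin 17 family, fell 8.85-fold (log2 change -3.15, SE 0.16), and C1qtnf3, which encodes a secreted C1q-related protein, fell 6.44-fold (-2.69, SE 0.19). Scube2, whose product helps release hedgehog proteins, fell 4.82-fold (-2.27, SE 0.14), and Smpd3, the neutral sphingomyelinase 2 gene, fell 4.76-fold (-2.25, SE 0.17). In Ad-Epas1 cells Sfrp5, Il17b (3.98), Slc35f1 (5.52), Slc16a14 (5.42) and Scube2 (4.87) lay no higher than Apoa1 in Ad-null cells (5.84), so the size of their fall depends on the background correction, as for 9 of the 38 named genes that fell. The transporter genes Slc35f1, Slc16a14 and Slc8a3, the last a sodium-calcium exchanger, changed by -2.74, -2.35 and -2.08 on the log2 scale, and a further, dimmer probe set of Slc35f1 by -1.04 (adjusted p = 0.00056). Matn1 at -2.02 and Cmtm5 at -1.95 completed the 10, whose adjusted p in limma lay between 7.7e-06 and 0.00098. Cmtm5 did not pass in an unequal-variance test per probe set (adjusted p = 0.0602).

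**Figure D2:**
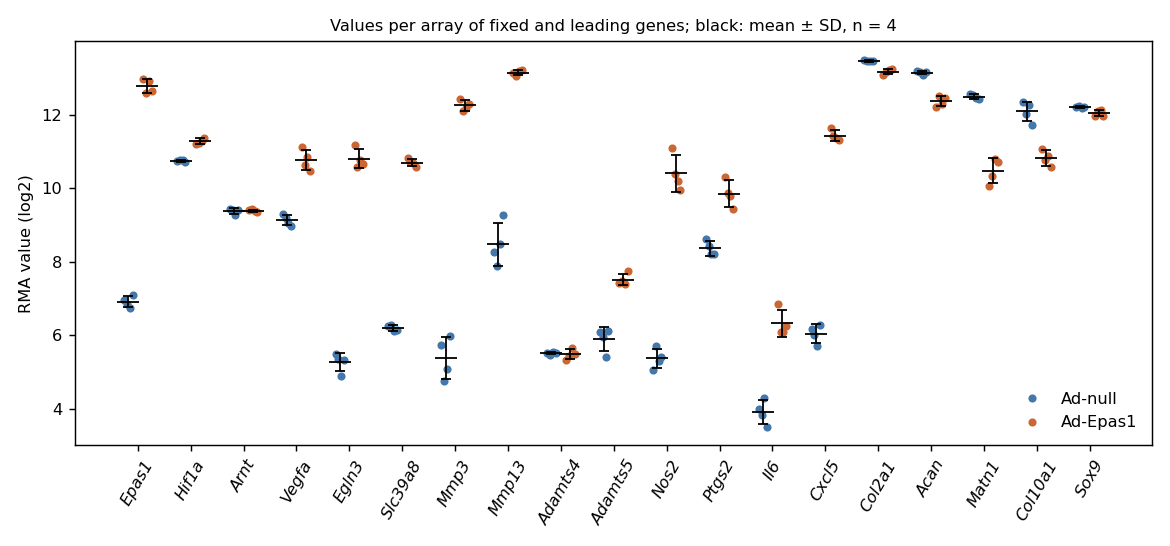
RMA values (log2, vertical) of 19 genes on each array, Ad-null in blue and Ad-Epas1 in orange, with black bars for the mean and SD of 4 arrays. Mmp3, Mmp13, Nos2, Egln3 and Slc39a8 lie above their Ad-null values on all 4 Ad-Epas1 arrays, whereas the groups overlap for Arnt and Adamts4. Adamts4 lies below Apoa1 in Ad-null cells (5.84) in both groups, so a change could go unseen.

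Hypoxia-inducible genes rose as a group, with 23 of 27 measured members higher, none lower and a median change of 1.07 on the log2 scale. Adm, which encodes the vasodilator peptide adrenomedullin, rose 17.3-fold (log2 change 4.11, SE 0.22), Angptl4, a regulator of lipoprotein lipase, rose 7.34-fold (2.88, SE 0.28), and Car12, a carbonic anhydrase, rose 4.92-fold (2.3, SE 0.12). Vegfa, the main growth factor for blood vessels, rose 3.11-fold from 9.13 ± 0.14 to 10.77 ± 0.27 (SD, n = 4, limma adjusted p = 0.00023). Epo, which encodes erythropoietin, had a mean of 5.29 in Ad-null and 5.49 in Ad-Epas1 cells (adjusted p = 0.55). Both means lay below Apoa1 in Ad-null cells (5.84), so a change of Epo could go unseen. Adjusted over the list alone, 24 members passed. The camera test of the list gave an adjusted p of 5.9e-29 with the preset correlation. The adjusted p was 0.015 with an estimated correlation, and 0.098 with an estimated correlation and the replicate block.

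Glycolysis genes rose likewise, with 12 of 16 members higher (13 adjusted over the list alone), none lower and a median change of 0.81. Slc16a3, a lactate exporter, rose 5.53-fold (log2 change 2.47, SE 0.15), and the enzyme genes Pfkp, Tpi1 and Eno2 rose 2.47-fold, 2.39-fold and 2.39-fold. Gapdh was at 12.98 in Ad-null and 13.14 in Ad-Epas1 cells (adjusted p = 0.26). As a list they had an adjusted p of 2.3e-14 in camera, 0.035 with an estimated correlation, and 0.098 with an estimated correlation and the block. Of the 10 HIF pathway components, 4 rose and 0 fell, the same counts as when adjusted over the list alone, with a median of 0.14 (camera adjusted p = 0.005, and adjusted p = 0.064 with an estimated correlation). The 4 were Egln3, its relative Egln1 (log2 change 1.07), Hif1a (0.53, SE 0.07, adjusted p = 0.003) and Vhl (0.47, adjusted p = 0.021 and 0.0503 with the block). A further probe set of Hif1a rose by 0.64 (adjusted p = 0.025). Egln1, Egln3 and Vhl all serve the degradation of HIF proteins. Arnt, which encodes the partner subunit of HIF-2alpha, had a change of 0.01 with a 95% interval from -0.15 to 0.18. Oxidative phosphorylation genes had a median of -0.08, and Sdhb alone of 23 fell (-0.37), alone also when adjusted over the list alone. The adjusted p of Sdhb was 0.025 in limma and 0.065 with the block, and that of the list was 0.038 in camera, 0.0546 with the block and 0.39 with an estimated correlation.

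Of 14 genes that earlier work had described as HIF-2alpha targets in chondrocytes, 10 rose and 1 fell, with a median change of 2.06 on the log2 scale. Slc39a8, the zinc importer ZIP8, rose 22.6-fold from 6.2 ± 0.07 to 10.7 ± 0.1 (SD, n = 4, limma adjusted p = 1.2e-07). Il6, an inflammatory cytokine gene, rose 5.32-fold (log2 change 2.41, SE 0.21, adjusted p = 0.00025), and Fas, a death receptor gene, was among the other members that rose, at 1.71. Col10a1, the collagen of hypertrophic chondrocytes, fell 2.4-fold from 12.09 ± 0.27 to 10.82 ± 0.21 (SD, n = 4, limma adjusted p = 0.0015). Adamts4 was at 5.52 ± 0.03 and 5.48 ± 0.13 (SD, n = 4, limma adjusted p = 0.9), Nampt at 8.48 and 8.76 (adjusted p = 0.07) and Ihh at 7.24 and 6.76 (adjusted p = 0.084). Adamts4 lay below Apoa1 in Ad-null cells (5.84) in both groups, so a change could go unseen. The Nampt values of the groups did not overlap, and the 95% interval of its change ran from 0.1 to 0.45. For the whole list the adjusted p was 1.7e-12 in camera, 0.015 with an estimated correlation, and 0.098 with an estimated correlation and the block. Adjusted over the list alone, 11 rose and 2 fell, and because the list was drawn from work on the same factor and cell type, its direction is not independent evidence.

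Matrix-degrading enzymes rose in 12 of 25 cases and fell in 2, with a median of 0.45. Beside Mmp3 and Mmp13, Mmp12 rose 7.88-fold (log2 change 2.98, SE 0.21), Mmp9 6.39-fold (2.68, SE 0.2) and Adamts5, an enzyme that cleaves aggrecan, 3.06-fold (1.62, SE 0.17, adjusted p = 0.00057). Mmp16 (-0.69) and Adamts12 (-0.63) fell. The list had an adjusted p of 5.5e-07 in camera, 0.015 with an estimated correlation, and 0.098 with an estimated correlation and the block, and 14 members rose and 2 fell when adjusted over the list alone. Protease inhibitors moved both ways: Serping1, the C1 inhibitor gene (3.16), Serpina3n (2.39) and Timp1 (1.33) rose and Timp3 (-0.57) fell among 10, where Timp1 and Timp3 encode inhibitors of metalloproteinases. Their median was 0.1 (camera adjusted p = 0.038, and adjusted p = 0.21 with an estimated correlation), and 3 rose and 2 fell when adjusted over the list alone. The camera call of the inhibitors ended in 4 of the 8 tests with a single array left out, with adjusted p from 0.018 to 0.059 over the 8.

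Cartilage matrix genes fell in 16 of 25 cases and rose in 2, with a median of -0.54. After Matn1, the largest falls were those of Matn3 and Mia, at -1.34 each. Acan, which encodes the main proteoglycan of cartilage, fell 1.71-fold from 13.14 ± 0.05 to 12.37 ± 0.14 (SD, n = 4, limma adjusted p = 0.001). Col2a1, the main collagen of cartilage, fell 1.22-fold (log2 change -0.29, SE 0.07, adjusted p = 0.046). Col2a1 at 13.46 and Acan at 13.14 in Ad-null cells, and Mmp13 at 13.14 in Ad-Epas1 cells, were near the highest value of the arrays (13.7 to 13.8), where saturation can shrink a change, so their folds may be understated. The genes of collagens that accompany type II collagen also fell, among them Col9a1 (-0.74), Col9a3 (-0.92) and Col11a2 (-1.02). Prg4, the joint lubricant lubricin, rose 8.53-fold (3.09, SE 0.21), and Dcn, the small proteoglycan decorin, rose by 0.89. As a list they had an adjusted p of 9.3e-07 in camera but 0.25 with an estimated correlation, and 18 fell and 4 rose when adjusted over the list alone. The call of Col2a1 ended with the block (adjusted p = 0.106) and with any 1 of the 8 arrays left out (0.0654 to 0.119), and it did not pass in the unequal-variance test per probe set (adjusted p = 0.0556), in which 10 of the 25 genes fell.

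Of 13 chondrocyte transcription factors, Runx1 rose (log2 change 2.09) and Mef2c (-0.64) and Sox6 (-0.46) fell, while 2 rose and 4 fell when adjusted over the list alone. Sox9, the master regulator of chondrocyte identity, was at 12.2 ± 0.02 and 12.04 ± 0.08 (SD, n = 4, limma adjusted p = 0.28). All 4 Ad-Epas1 values of Sox9 lay below all 4 Ad-null values, with a change of -0.17 (95% interval -0.33 to 0), so a small fall is not excluded. The median of these factors was -0.16 and their mean 0.01 (camera adjusted p = 0.39, downward). A further probe set of Mef2c had a change of -0.07. Of 11 genes of hypertrophy and mineralisation, 5 fell and 2 rose, or 6 and 3 adjusted over the list alone, with a median of -0.49 and a camera adjusted p of 0.056. Pth1r, the receptor of parathyroid hormone and its related peptide (-1.3), Alpl, the alkaline phosphatase of mineralising cells (-0.92), and Sp7, a transcription factor of bone cells (-0.84), fell with Col10a1, while Mmp13 and Ank (0.66) rose. A further probe set of Alpl fell by 0.4 (adjusted p = 0.035). In the unequal-variance test per probe set 2 of the 11 fell and 1 rose. Genes of fibroblasts and of dedifferentiating chondrocytes had 2 of 17 members that rose, Pdgfra (1.56) and S100a4 (1.32), and 6 that fell, led by the smooth muscle and contractile genes Tagln (-1.28) and Acta2 (-1.17). Their median was -0.09 (camera adjusted p = 0.069), 2 rose and 7 fell when adjusted over the list alone, and Col1a1 was at 11.02 and 10.92 (adjusted p = 0.82).

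**Figure D3:**
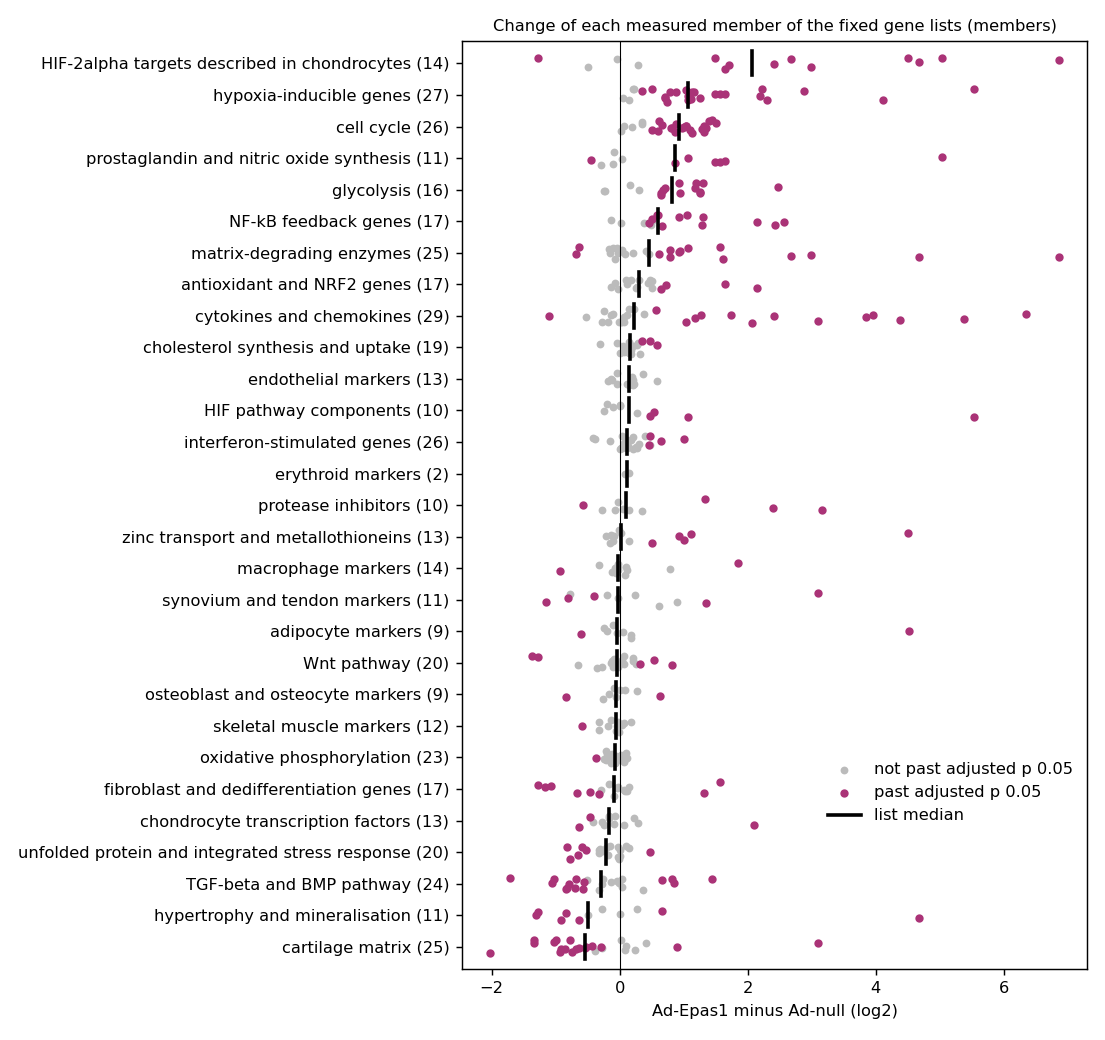
Change on the log2 scale (horizontal, Ad-Epas1 minus Ad-null) of each measured member of the 29 gene lists (vertical, number of members in brackets), with members past an adjusted p of 0.05 in purple, others in grey and a black bar at the list median. Medians run from 2.06 for HIF-2alpha targets described in chondrocytes to -0.54 for cartilage matrix.

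Cytokine and chemokine genes rose in 13 of 29 cases, and 1, the macrophage growth factor gene Csf1, fell (log2 change -1.1). Ccl5, which attracts T cells and monocytes, rose 20.7-fold (4.37, SE 0.13), and Ccl2, a monocyte attractant, rose 15.5-fold (3.95, SE 0.22). The cytokine genes Il1b, at 3.33 and 3.2, and Tnf, at 5.05 and 5.28, did not pass (adjusted p = 0.71 and 0.35). These levels lay below Apoa1 in Ad-null cells (5.84), so a change of Il1b or Tnf could go unseen. The median was 0.22, and 14 rose and 2 fell when adjusted over the list alone. For the whole list the adjusted p was 9.1e-08 in camera, 0.035 with an estimated correlation, and 0.23 with an estimated correlation and the block. NF-kB feedback genes, which this inflammatory pathway induces and several of which regulate it in turn, rose in 12 of 17 cases (14 adjusted over the list alone) and fell in 0, with a median of 0.59. Nfkbiz (2.57), Bcl3 (2.43), Sod2 (2.15) and Tnfaip2 (1.3) led them, and Nfkbia, the gene of the inhibitor IkB-alpha, rose by 1.28. Their adjusted p was 3.8e-15 in camera, 0.035 with an estimated correlation, and 0.17 with an estimated correlation and the block.

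Genes of prostaglandin and nitric oxide synthesis rose in 6 of 11 cases and 1, Ptgis, fell (log2 change -0.45), with a median of 0.86. Ptgs2, the inducible cyclooxygenase 2, rose 2.79-fold from 8.37 ± 0.2 to 9.85 ± 0.37 (SD, n = 4, limma adjusted p = 0.0016), and Ptges, a prostaglandin E synthase, rose 3.11-fold (1.64, SE 0.27). Arg2, an arginase, which uses the same substrate as Nos2, rose 2.96-fold. The list had an adjusted p of 8e-04 in camera and 0.2 with an estimated correlation, and 6 rose and 1 fell when adjusted over the list alone. Interferon-stimulated genes had a median of 0.12, with 4 of 26 higher, 0 lower and 7 higher when adjusted over the list alone. The 4 were Stat2 (1), Ifih1 (0.64), Isg15 (0.48, adjusted p = 0.049 and 0.0713 with the block) and Irf1 (0.46), whereas Mx1 was at 3.19 and 3.22 and Cxcl10 at 6.97 and 6.58 (adjusted p = 0.93 and 0.19). As a list they had an adjusted p of 0.00075 in camera, 0.035 with an estimated correlation, and 0.12 with an estimated correlation and the block. In the unequal-variance test per probe set 2 of the 26 rose and without the replicate 3 arrays 1, and since both viruses are adenoviruses, the comparison does not show what infection itself does to these genes.

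Cell cycle genes rose in 21 of 26 cases (23 adjusted over the list alone) and fell in 0, with a median of 0.93. Top2a, a topoisomerase of dividing cells, rose 1.51 on the log2 scale, the proliferation marker gene Mki67 1.44, the cyclin gene Ccna2 1.39 and Birc5, which encodes survivin, 1.35. E2f1 was at 6.7 and 6.72 and Mcm2 at 8.44 and 8.5 (adjusted p = 0.92 and 0.84). For the whole list the adjusted p was 5.6e-24 in camera and 0.035 with an estimated correlation, and it was the only one of the 29 to pass with an estimated correlation and the block together (adjusted p = 0.048). With an estimated correlation the p-value of camera is limited by the few arrays, and the block limits it further. A call lost there can therefore reflect low power. With the block and the preset correlation, the camera adjusted p was 2.8e-25 for hypoxia-inducible and 1e-11 for glycolysis genes.

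Genes of the TGF-beta and BMP pathways fell in 10 of 24 cases and rose in 4, with a median of -0.3. Chrdl1, a BMP antagonist (log2 change -1.71), Tgfb2 (-1.05) and Bmp7 (-1.03) fell, as did the BMP-induced genes Id1 (-0.7) and Id3 (-0.82), whereas Id2 (0.81), Gdf5, a growth factor of joint formation (1.44), and Smad7, an inhibitor of the pathway (0.85), rose. A further probe set of Gdf5 had a change of 0.57 (adjusted p = 0.098). The list had an adjusted p of 0.0048 in camera and 0.26 with an estimated correlation, and 12 fell and 5 rose when adjusted over the list alone. Of 20 Wnt pathway genes, 3 rose and 2 fell, or 3 and 3 adjusted over the list alone, with a median of -0.04 (camera adjusted p = 0.78). The Wnt antagonist gene Frzb (-1.27) and the feedback inhibitor gene Nkd1 (-1.37) fell, and the receptor gene Lrp5 (0.81), Ctnnb1 (0.32) and Wnt5a (0.54, adjusted p = 0.025 and 0.0866 with the block) rose, of which 1 passed in the unequal-variance test per probe set.

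Genes of zinc transport and metallothioneins rose in 5 of 13 cases, also when adjusted over the list alone, and fell in 0. After Slc39a8, the zinc-binding metallothionein genes Mt1 (2.15-fold, log2 change 1.11, SE 0.15, adjusted p = 0.0027) and Mt2 (0.92) and the importer gene Slc39a14 (1.01) rose most. Slc39a1 rose by 0.5. The median was 0.02 and the mean 0.58 (camera adjusted p = 0.0094, upward, and adjusted p = 0.11 with an estimated correlation), and the median ranged from -0.027 to 0.172 when single arrays were left out. Without the replicate 3 arrays 3 of the 13 rose, and in the unequal-variance test per probe set 2, without Mt1 (adjusted p = 0.0823) and Mt2 (0.137). Antioxidant and NRF2 genes rose in 4 of 17 cases, or 7 adjusted over the list alone, and fell in 0. They were Sod2, the mitochondrial superoxide dismutase, which is also in the NF-kB list, Gpx3, a secreted glutathione peroxidase (1.65), Fth1, the ferritin heavy chain (0.72), and Gsr, the glutathione reductase (0.65). The NRF2 target genes Hmox1, at 10.22 and 10.08, and Nqo1, at 8.83 and 9.27, did not pass (adjusted p = 0.62 and 0.25). The median was 0.3, with an adjusted p of 2.1e-06 in camera and 0.1 with an estimated correlation.

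Genes of the unfolded protein and integrated stress responses fell in 5 of 20 cases, or 11 adjusted over the list alone, and 1, Sdf2l1, rose (log2 change 0.47) under both adjustments. Chac1 (-0.82), Atf3 (-0.78), Ddit3 (-0.65) and Trib3 (-0.59, adjusted p = 0.02 and 0.0614 with the block), which are induced by the transcription factor ATF4, fell, whereas the chaperone gene Hspa5 was at 9.8 and 9.6 (adjusted p = 0.16). The median was -0.21, with an adjusted p of 0.0033 in camera and 0.27 with an estimated correlation. Of 19 genes of cholesterol synthesis and uptake, 3 rose, or 4 adjusted over the list alone, and 0 fell. The 3 encode enzymes of the pathway: Hsd17b7 (0.58), Nsdhl (0.47) and Ebp (0.34, adjusted p = 0.03 and 0.0652 with the block). The median was 0.16, with an adjusted p of 8e-04 in camera and 0.35 with an estimated correlation. Without the replicate 3 arrays 0 of the 19 rose.

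Markers of other cells that cartilage preparations can hold did not pass as lists in camera. Macrophage markers had a median change of -0.02 and a mean of 0.09 over 14 genes (camera adjusted p = 0.87, upward). Cd14, a receptor for lipopolysaccharide (log2 change 1.84), rose and Laptm5 (-0.94) fell, whereas Ptprc was at 3.39 and 3.33 and Adgre1 at 4.12 and 4.21. Endothelial markers had a median of 0.15 (camera adjusted p = 0.15), with 0 of 13 past the threshold in limma, 3 at an unadjusted p under 0.05 and 0 in an unequal-variance test per probe set. Pecam1, an endothelial adhesion gene, was at 5.51 and 5.33 (adjusted p = 0.66). Osteoblast and osteocyte markers had a median of -0.06 over 9 genes, with Sp7 lower and Ifitm5 (0.63) higher (camera adjusted p = 0.92). Skeletal muscle markers had a median of -0.06 over 12, with Tnni2 (-0.59) lower (adjusted p = 0.29). Synovium and tendon markers had a median of -0.02 and a mean of 0.26 over 11 (adjusted p = 0.78, upward). Prg4 and Pdpn (1.35) rose and the tendon transcription factor gene Mkx (-1.15), Cd55 (-0.81) and Kera (-0.4) fell. Adipocyte markers had a median of -0.04 and a mean of 0.41 over 9 (adjusted p = 0.9, upward), with Fabp4 higher, Pparg (-0.61) lower and Adipoq at 3.83 and 3.8. The 2 measured erythroid markers had a median of 0.11 (adjusted p = 0.52), and 0 of them passed in limma, at an unadjusted p under 0.05 or in the unequal-variance test. Adjusted over the list alone, 2 macrophage markers rose and 2 fell, 4 synovium and tendon markers rose and 4 fell, and the counts of the other lists of this kind stayed as given.

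In all, 18 of the 29 lists passed in camera with the preset correlation, 14 upward and 4 downward. With an estimated correlation 8 passed, all upward: hypoxia-inducible genes, glycolysis, HIF-2alpha targets in chondrocytes, matrix-degrading enzymes, cytokines and chemokines, NF-kB feedback genes, interferon-stimulated genes and the cell cycle. With the replicate block these numbers were 17 and 1, the latter from a test with low power at 8 arrays. The fry test, which does not set a list against other genes, passed 23.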

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

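The count over other splits of the arrays was planned before its result was seen, and no test in this part was chosen afterwards. Of the 35 ways to split the 8 arrays into 4 and 4, only 1, the true grouping, gave as many as 2869 probe sets past the threshold. That share is under the planned level of 0.05, which argues against chance as the source of that number. It is also the smallest share that 35 splits can give, so chance is not excluded. The other splits mix the viruses, which widens the spread within their groups and lowers their counts. The highest other split gave 58 and set replicates 1 and 2 of both groups against replicates 3 and 4. Of the 8 splits that part all pairs of equal replicate number, the highest besides the true one gave 0, but 8 splits are too few for a share under 0.05, and the 7 others mix the viruses across replicates.

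In 13 of 278 groups of 4 arrays 1 value lay far from the other 3, where 1 in 20, or 13.9, would be met by chance. Among genes of the HIF pathway, metal binding and glycolysis, these were Arnt on Ad-null array 3 (9.26, nearest other value 9.4), Mt1 on Ad-Epas1 array 1 (11.51, nearest 11.41) and Pfkp on Ad-Epas1 array 1 (10.05, nearest 9.73). Among genes of matrix and proteases they were Col2a1 on Ad-null array 1 (13.49, nearest 13.45), Mmp9 on Ad-Epas1 array 3 (7.7, nearest 8.01), Serping1 on Ad-null array 1 (5.32, nearest 4.8) and Serpina3n on Ad-null array 1 (10.58, nearest 10.2). The cyclin gene Ccna2 stood low on Ad-Epas1 array 4 (8.32, nearest 8.61) and the monocyte receptor gene Cd14 on Ad-null array 3 (5.12, nearest 5.47). The BMP antagonist gene Chrdl1 stood high on Ad-null array 1 (8.1, nearest 7.7) and on Ad-Epas1 array 4 (6.58, nearest 5.95). The mean of the antioxidant and NRF2 genes was highest on Ad-Epas1 array 1 (9.38, nearest 9.18), which also had the highest score on the first principal component (46.11, nearest 31.71).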

How the results depend on the processing

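The test without the replicate 3 arrays of both groups and, for named genes and lists, the unequal-variance test were chosen after the data had been seen. No probe set called in both the reported test and an alternative changed direction. The replicate block, variance trend, brighter probe sets, unequal-variance test and 1 probe set per gene leave each change as it was. Direction could not differ under those settings. The count of 2869 became 2407 with the replicate block, 3777 with a variance trend, 2948 after quantile normalization, 2598 after centring, 2994 with array weights, 4068 among the probe sets at or above the median brightness, 1977 with the unequal-variance test and 3336 with 1 probe set per gene. It ranged from 2029 to 2384 with single arrays left out and was 1649 without both replicate 3 arrays, 1560 of them shared with the reported calls. Higher probe sets then numbered 955, and up to 1327 with single arrays left out. Lower probe sets numbered 694 without both replicate 3 arrays, 834 without Ad-null 1, 913 without Ad-null 2, 925 without Ad-null 4, 881 without Ad-Epas1 1, up to 1129 with other single arrays left out, and 2221 among the brighter probe sets. The replicate block kept 2130 of the 2869 reported calls (74.2%), so its count of 2407 includes calls that the reported test did not make. Fewer arrays lower the power of the test, and the other causes were not tested.

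Of 104 named genes past the threshold, 94 stayed past it with each array left out in turn and 88 under every other setting that gave a value but the unequal-variance test, which kept 86. That test ended the calls of Cmtm5, Col2a1, Mt1, Mef2c, Alpl, Ptges, Ifih1, Isg15, Trib3, Mt2, Nsdhl, Lrp5, Wnt5a, Sp7, Ifitm5, Tnni2, Cd55 and Pparg. The replicate block ended the calls of Col2a1, Vhl, Isg15, Sdhb, Trib3, Ebp and Wnt5a and of no other named gene. With single arrays left out, calls ended for Col2a1 (any array), Isg15 (all but Ad-Epas1 4), Ebp (all but Ad-null 3), Tnni2 (all but Ad-null 4), Sdhb (all but Ad-null 3 and Ad-Epas1 4), Ifitm5 (all but Ad-Epas1 1 and 4), Vhl (Ad-null 1, 2 and 3, Ad-Epas1 1 and 2), Wnt5a (Ad-null 2, 3 and 4, Ad-Epas1 2 and 4), Sox6 (Ad-null 3 and 4, Ad-Epas1 1 and 2) and Trib3 (Ad-null 1, 2 and 4). Arnt, never past the threshold, ranged from -0.024 without Ad-null 3 to 0.03 and was -0.019 without both replicate 3 arrays, and Adamts4 ranged from -0.093 to 0.014, the last without Ad-Epas1 1.

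Of 289 list results under settings other than single arrays left out, 259 kept direction and call. With an estimated correlation, in fry, with the block and with a variance trend the list median is that of the reported test. Only the call could change there. With an estimated correlation the calls ended for HIF pathway components (median 0.141), protease inhibitors (0.099), cartilage matrix (-0.543), prostaglandin and nitric oxide synthesis (0.861), oxidative phosphorylation (-0.084), unfolded protein and stress response (-0.207), antioxidants (0.298), zinc transport (0.023), cholesterol (0.158) and TGF-beta and BMP (-0.301). The oxidative phosphorylation call also ended with the replicate block (-0.084, adjusted p = 0.0546), quantile normalization (-0.08), the brighter probe sets (-0.084), both replicate 3 arrays left out (-0.084) and the mean over probe sets (-0.083), with medians from -0.112 to -0.086 and 4 of 8 calls kept when single arrays were left out. The block ended no other camera call. Protease inhibitors lost theirs among the brighter probe sets (0.196), with medians from 0.059 to 0.137 without single arrays. Hypertrophy (-0.486; -0.593 to -0.406) and fibroblast genes (-0.094; -0.179 to -0.054) passed with a variance trend, in fry and in 2 of 8 tests without an array, and the Wnt (-0.042), endothelial (0.154) and muscle (-0.059) lists passed in fry.

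Of 58 counts of list members that rose or fell, 14 moved by over 1.5 times in the unequal-variance test, the largest being cartilage matrix genes that fell (16 to 10) and hypertrophy genes that fell and zinc genes that rose (5 to 2 each). The others that moved were 4 or fewer at first. Those that moved numbered 10 among the brighter probe sets, 4 with the block, 6 with a variance trend, 12 without both replicate 3 arrays, and 3 to 8 without single arrays, where only counts of 3 or fewer moved.

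Medians near 0 changed sign. Zinc transport was at -0.002 with array weights, -0.004 without both replicate 3 arrays and -0.027 to 0.172 without single arrays, its camera call kept. Among the brighter probe sets the medians were 0.117 for macrophage, -0.044 for endothelial, 0.017 for osteoblast and 0.608 for synovium markers, where fewer members remained, and the adipocyte median was 0.015 with the mean over probe sets. Without single arrays the ranges were -0.068 to 0.013 for macrophage, -0.085 to 0.012 for osteoblast, -0.067 to 0.03 for synovium and -0.077 to 0.018 for adipocyte markers. The deposited values carry no signal over background, so what dim probe sets could show is not known.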

Other observations

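The tests on macrophage markers, on neighbours of the Dlk1-Dio3 locus, on imprinted genes with Cdkn1c, on overlapping genes, on named neighbours and without the replicate 3 arrays, and the lists of acute-phase, complement, angiogenic and class I genes, were chosen after the results they bear on had been seen. Angiogenic factors and their receptors rose in 10 of 17 cases and fell in 0, with a median change of 1.13 on the log2 scale. Apln, which encodes the peptide apelin, rose 14.7-fold (log2 change 3.88, SE 0.2), Pgf, the placental growth factor, 14.4-fold (3.85, SE 0.25), Prok2, the prokineticin 2 gene, 14.2-fold (3.83, SE 0.3) and Vegfd 5.66-fold (2.5, SE 0.26), whereas Vegfc was at 5.45 and 5.72 (adjusted p = 0.56) and the apelin receptor gene Aplnr at 4.83 and 4.97 (adjusted p = 0.66). Of 17 complement genes, 7 rose and 1, Cd55, fell, with a median of 0.1. Cfb, the complement factor B gene, rose 17.5-fold (4.13, SE 0.16), Serping1 rose by 3.16 and C1s1 by 1.86, and C1qa was at 5.43 and 5.53 (adjusted p = 0.76). Class I antigen presentation genes rose in 6 of 13 cases and fell in 0, with a median of 0.33. H2-Q10 was among those that rose, at 3.28, and Tapbp, the gene of tapasin, at 1.1, while B2m was at 11.73 and 11.75 (adjusted p = 0.96). Apln (5.2), Pgf (5.17), Prok2 (4.6), C1s1 (4.07) and H2-Q10 (5.81) in Ad-null cells lay no higher than the hepatocyte marker Apoa1 (5.84), so the size of their rise depends on the background correction and is not exact. The H2 genes are close relatives whose probes cannot be kept apart with certainty. The camera adjusted p of these lists, which hold genes seen to rise, was 1.7e-12 for angiogenic, 0.00032 for complement and 4.8e-07 for class I genes, or 0.0026, 0.014 and 0.0071 with an estimated correlation. With an estimated correlation and the replicate block it was 0.035, 0.054 and 0.044, so the complement genes no longer passed, while 10, 8 and 5 members rose.

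Cytosolic ribosomal protein genes, a list written before its values were seen, had a median of -0.07, with 0 of 19 past the threshold in limma, 1 at an unadjusted p under 0.05 and 0 in the unequal-variance test (camera adjusted p = 0.15). The mean of 83 probe sets of small nucleolar, Cajal body and Y RNAs was 8.29 and 8.28 on Ad-null arrays 3 and 4 and 8.36 and 8.41 on Ad-Epas1 arrays 3 and 4. It was 7.68 and 6.98 on Ad-null arrays 1 and 2 and 7.64 and 7.59 on Ad-Epas1 arrays 1 and 2.

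At the imprinted Dlk1-Dio3 locus 51 of 71 probe sets (53 with the replicate block) fell and 0 rose, with a median of -1.03 (95% bootstrap interval -1.17 to -0.82), among them Rian (log2 change -1.25), Mir154 (-1.86), Meg3 (-0.62, and -1.17 and -1.57 on brighter probe sets that also cover microRNAs) and Dlk1 (-0.55), whereas Dio3 was at 4.58 and 4.71 (adjusted p = 0.75). The locus was in none of the lists fixed in advance and was singled out after its fall had been seen. Several of its probe sets share the transcripts Meg3, Rian, Rtl1 or Mirg, so its members are not independent of each other. Bootstrap intervals here and in the next paragraph were drawn over the members of a set, not over arrays, so they do not measure replicate spread. Taken by replicate number 1 to 4, the locus medians were -1.09, -1.05, -0.76 and -1.02. Mir154 fell from 5.73 to 3.87 and others started lower, such as Mir379 (4.84), all below Apoa1 (5.84). The size of such falls depends on the background correction, whereas Rian fell from 10.54 to 9.29. A shift of all probe sets named for microRNAs is argued against by the 511 elsewhere, whose median was 0.03 (0.01 to 0.06). This holds only as far as they were bright enough to show a fall, because brightness was not matched to the locus. The higher small RNA signal of replicates 3 and 4 was present in both groups, so leaving these arrays out could say little about it. The locus median of -1.09 without replicate 3 and of -1.13 without replicates 3 and 4 shows only that the fall does not rest on those arrays. The 27 probe sets of genes within 1 Mb outside the locus had a median of 0.06 (-0.09 to 0.09). Their brightness was not matched to the locus either. The median of 23 imprinted genes elsewhere was -0.31 (-0.42 to 0.02), or -0.31 (-0.44 to -0.04) with Cdkn1c (-1.65), left out at first because its value had been seen. Of the 23, 9 fell (8 with the block), led by Magel2 (-1.29) and Phlda2 (-1.05), and 1 rose. These 23 genes were lower as a list (camera adjusted p = 0.00032, and adjusted p = 0.12 with an estimated correlation). As far as their probe sets were bright enough to show it, neither the wider region nor imprinted genes in general shared the whole fall. A candidate explanation, as a hypothesis, is lower transcription of the long noncoding RNA genes of this locus when HIF-2alpha is supplied, which remains untested here, because the probe sets do not tell a microRNA precursor from the longer transcript around it. This hypothesis would not by itself cover Dlk1, a protein-coding gene that fell as well (-0.55).

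Acute-phase and innate defence genes rose in 14 of 18 cases and fell in 0, with a median of 1.91 (95% bootstrap interval 0.74 to 3.84), among them Slpi, a protease inhibitor of secretions, at 4.48 and Chil1, a chitinase-like protein gene, at 3.26 (camera adjusted p = 7.1e-20, and adjusted p = 0.0071 with an estimated correlation, or 0.022 with the replicate block as well, where 13 members rose). RNA of macrophages, hepatocytes or neutrophils is argued against by macrophage markers, with a median of -0.02 (-0.07 to 0.09) although Cd14 rose (1.84), by hepatocyte markers, with -0.02 (-0.11 to 0.09), and by neutrophil markers, with 0.07 (-0.07 to 0.09). Alb, one of the most abundant liver transcripts, was at 3.67 and 3.52, Ttr at 5.03 and 5.12, S100a8 at 2.76 and 2.62 and Lyz2 at 4.72 and 4.68, and 0 of 14 hepatocyte and 0 of 12 neutrophil markers passed in limma or in the unequal-variance test, with 0 and 1 at an unadjusted p under 0.05. Expression by the chondrocytes themselves may account for the rise, as a hypothesis, but RNA of synovial or fibroblast cells stays open, because the synovium and tendon markers (median -0.02) and the fibroblast genes (-0.09) moved both ways, with Prg4 (3.09), Pdpn (1.35) and Pdgfra (1.56) higher and Mkx (-1.15), Cd55 (-0.81), Tagln (-1.28), Acta2 (-1.17) and Tnc (-1.08) lower, and because Col1a1 (11.02) and Acta2 (12.1) were bright enough in Ad-null cells to hide a small share. Whether the rise follows from HIF-2alpha directly or through secreted cytokines was not tested, and the list includes Saa2, Hp and Lbp, which prompted it.

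Genes that rose by 1 or more on the log2 scale lay side by side along chromosomes more often than in shuffled gene orders, with 25 adjacent pairs among 392 such genes against a median of 7 and a maximum of 19 in 10000 shuffles (permutation p = 1e-04, the smallest they can give). Leaving out pairs with related symbols, whose probes could measure each other's transcripts, left 14 pairs, such as Fas with Ch25h, Cebpd with Spidr and Ndrg1 with St3gal1, against a shuffled median of 6 and a maximum of 16 (permutation p = 0.0026). Leaving out overlapping genes as well left 12, against a median of 5 and a maximum of 15 (permutation p = 0.0093). Against these shuffles, shared probe signal of these kinds would not account for the whole excess. The shuffles spread the rises over all 21994 placed genes whatever their brightness. They cannot tell an excess from expressed genes lying together along chromosomes. Of the 14 pairs, 5 join a gene to a RIKEN, Gm or microRNA transcript, such as Pfkfb3 with Gm13293, and the other 9, against shuffled orders of named genes with a median of 5 and a maximum of 17, did not pass a p of 0.05 (permutation p = 0.1). Signal that such transcripts share with the gene beside them may account for part of the excess beyond related genes. The lost call does not show it, because 9 pairs still lay above the median of 5 and so few pairs give little power. The question stays open, and a shared regulatory element was not tested.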
